A study of Mus musculus with 40 samples.

How the data were processed

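Single cells of mouse gluteus medius, a muscle of the hip, were profiled by droplet RNA sequencing in 40 libraries made with the 10x Genomics Chromium v2 reagent kit, per the labels' protocols. The mice carried either a conditional Acvr1 allele that encodes the R206H substitution, called FOP here after fibrodysplasia ossificans progressiva, or 2 wild-type Acvr1 copies, called WT. Acvr1 encodes a type I receptor of the bone morphogenetic protein (BMP) family, and the protocol cites work in which this allele made the receptor respond to activin A. Both genotypes carried a tamoxifen-inducible Cre recombinase at the Rosa26 locus. Per the series' design text, the model was started with tamoxifen, and injured and control muscle was collected 5 days after muscle injury. The labels name the right muscle as injured and the left as control.

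The 40 libraries fall into 5 sets, each with its own batch label. The labels of 4 sets carry D1, D2, D4 or D6, which they do not spell out, and those of the remaining set carry no such mark, so that it is called undated here. A D number cannot be told apart from its batch. Each set holds 2 libraries per genotype and muscle, except the undated set with 3 WT injured libraries and 1 WT control library. The undated and D2 sets were each sequenced on 1 flowcell, and the libraries of D1, D4 and D6 were spread over 3 others, per the labels. The 20 groups together give 10 FOP injured, 11 WT injured, 10 FOP control and 9 WT control libraries. The labels name no animals, so libraries could not be paired, and p-values measure only the spread between these libraries, part of which may be technical.

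The deposited matrices hold whole-number UMI counts per gene and cell barcode, not normalized. Per the submitters' processing notes, Cell Ranger, Seurat 3.0 and the mouse build mm10 were used; their roles, the annotation and the filters on cells are not given in the sources used here. The deposited matrices hold 58624 barcodes and 25127 features, of which 27 are named for vectors or tags. The feature names join a symbol, a chromosome and a strand, and 327 symbols on 958 features were summed, which left 24496. The lowest UMI count of a deposited barcode ran from 937 to 5954 between libraries, so the authors' matrices had been restricted to different depths before deposit. Counts near this limit can remove small cells from some libraries only, and shares of cells depend on it.

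Barcodes with at least 200 genes, at least 400 UMIs and at most 15% mitochondrial UMIs were kept, which removed 280 barcodes for few genes and 510 for their mitochondrial share, some of them for both, and left 57960. Scrublet marked 231 barcodes, 0.399%, at the threshold it set itself and had therefore not worked. The barcodes with the highest doublet scores were removed instead, at an expected rate that grew in proportion to the cells of a library, which took out 710 barcodes, 1.22%. The 57250 cells analysed ran from 908 to 2326 per library. Total UMI counts ran from 3271818 to 19057662 per library and median UMI counts per cell from 2043 to 11070.5. Counting error is therefore smallest for abundant genes in the large classes and limits rare classes and low genes.

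Counts were scaled to 10000 per cell and log-transformed for clustering only. The 2500 most variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1.0 gave 35 clusters. A cluster was named X-like only from markers fixed before the data were examined, and 29 clusters received one of 15 names. The other 6 clusters, with 14.3% of cells, stayed unnamed. The named classes were fibroblast-like (10135 cells), monocyte/macrophage-like (8503), B cell-like (8364), endothelial-like (7830), T cell-like (7571), muscle stem/progenitor-like (2075), Schwann/glial-like (1719), mural-like (994), tenocyte-like (425), dendritic cell-like (412), perineurial-like (328), lymphatic endothelial-like (270), NK cell-like (183), neutrophil-like (128) and myofibre-like (104).

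UMI counts were summed per library and class, with at least 20 cells required. The sums were tested with edgeR 4.0.16 (TMM normalization, filterByExpr, quasi-likelihood F-test, set as a covariate), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are log2 with a standard error (SE) that was taken from the F statistic. Levels are summed counts scaled to the same total per library (CPM), with the SD over libraries. DESeq2 1.42.0 was run as a second tool. The comparisons were FOP against WT in injured muscle and in control muscle, injured against control muscle within each genotype, the genotype by injury interaction and the genotype by set interaction. Shares of cells were compared with exact permutation tests, two-sided, in which genotype or muscle was relabelled within sets (between 3888 and 12960 relabellings), adjusted over the 15 classes. The 25 gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation, and with fry. fry asks whether the genes of a list move on balance in 1 direction, or in its mixed form in either. Where 2 lists share a gene it counts under both.

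These comparisons, tests, gene lists, cell type markers and most alternatives were set before the data were examined. So was the rule for the genes the text names. For FOP against WT in injured fibroblast-like and monocyte/macrophage-like cells these were, among genes past the threshold with a mean log2 CPM of at least 4, the 8 higher and 8 lower with the largest changes. To these came up to 4 members of each list past the threshold and, always, Acvr1, Inhba, Id1, Sox9, Runx2 and Scx. For other classes, for control muscle and for interactions the numbers were 3 and 3 with up to 2 per list, and for injured against control muscle 8 and 8 with up to 3 per list. The text takes examples from those genes and says where a gene was chosen after its values were seen. Some of those genes are not reported here.

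Each test was run on simulated counts with 200 changed genes of known size. All genes were given the same spread between libraries (negative binomial dispersion 0.1) and no differences between sets. Changed genes had a mean count of at least 10 per library. The shares recovered below therefore do not cover lower genes, or genes that vary more between libraries or sets. In the simulation of FOP against WT in injured fibroblast-like cells, edgeR recovered 86% of genes changed 2-fold and 100% of genes changed 4-fold, and called 9 unchanged genes of 10641. The shares recovered were 75% and 99% for monocyte/macrophage-like cells, 43% and 85% for T cell-like cells, and 60% and 100% for fibroblast-like cells of control muscle. They were 32% and 98% for the interaction in fibroblast-like cells and 18% and 63% in monocyte/macrophage-like cells. For the genotype by set interaction they were 0% and 5% in fibroblast-like cells and 0% and 0% in monocyte/macrophage-like cells, so a count of 0 there says little.

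Replicate libraries were compared with a chi-square test over genes, and all 21 pairs differed by more than sampling noise (5.72 to 95.6 per degree of freedom) and shared at most 8 barcodes, so none was counted as 1 library. Xist, expressed from the inactive X chromosome, had 0 to 3 UMIs per library and Y-linked genes 620 to 2100, so every library came from male cells. The 3' tags of Acvr1 lie outside the mutated codon, so the genotype of a library was not checked. The alternatives were DESeq2, DESeq2 size factors in edgeR, no filter on low counts, at least 50 cells, at most 100 cells, no set covariate, doublets kept, at most 5% mitochondrial UMIs, Leiden resolutions 0.5 and 2.0, and a covariate for the ratio of Y-linked to Xist counts. Each set and each library was also left out in turn. Added after the data were seen were fits without 4 libraries with a doubted label, covariates for depth and for the flowcell, single clusters, the unnamed cluster 13 counted as mural-like, and 1 UMI minimum for all libraries of a set and muscle. Levels of 7 transcripts in each class, as a measure of free RNA, were also added then. Other tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3.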

Results

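Heterotopic ossification in FOP, in which muscle and connective tissue are replaced by bone after injury, was examined at an early stage in 57250 single cells of mouse gluteus medius. The data are 40 libraries, with injured and control muscle of FOP mice (10 and 10 libraries) and of WT mice (11 and 9). They belong to 5 sets, each with its own batch label, and libraries are named here by set, genotype, muscle and replicate number. Total UMI counts ran from 3271818 to 19057662 per library. Median UMI counts per cell were 6890 ± 2769 (SD, n = 10) in FOP injured and 5125 ± 2284 (n = 11) in WT injured libraries, against 2685 ± 623 (n = 10) and 2725 ± 675 (n = 9) in FOP and WT control libraries. Acvr1 itself, with the file identifier Acvr1_2_-_1, lies on chromosome 2 from 58446438 to 58566828 in mm10 (RefSeq annotation, protein coding).

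In 4 libraries the makeup of cells raised doubt about the label. Monocyte/macrophage-like cells made up 0.952% of the library labelled D1 WT injured 2 and 7.74% of that labelled undated WT injured 3. They made up 19.2% of the library labelled D1 WT control 2 and 6.90% of that labelled D6 FOP control 2. The last value and that of undated WT injured 3 are not apart from all others, with 7.69% in D6 WT injured 1 and 6.81% in D2 WT control 2, which were not doubted. All 4 were kept under their labels, and counts of genes are also given without them, an alternative chosen after the data were seen.

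The makeup of the injured muscle was compared between genotypes to ask which cell types differ in the early lesion. Schwann/glial-like cells, which ensheath axons, made up a smaller share in FOP, with 1.40% ± 1.23 of cells (SD, n = 10) against 2.94% ± 1.63 (n = 11) in WT. The mean within-set difference was -1.56 percentage points and was negative in 5 of 5 sets (exact permutation p = 0.000926, adjusted p = 0.0139). Cells named mural-like, a class of pericytes and vascular smooth muscle, made up 0.640% ± 0.457 in FOP against 1.47% ± 0.747 in WT, a difference of -0.83 points in the same direction in 5 of 5 sets (exact permutation, adjusted p = 0.0249). This class left out the unnamed cluster 13 (2881 cells, against 994), led by the pericyte genes Kcnj8, Abcc9 and Rgs5, which scored alike for mural and endothelial markers. With cluster 13 counted as mural-like, a choice made after the data were seen, the shares were 4.85% ± 1.89 and 7.76% ± 2.37, which did not pass (difference -2.82 points, lower in 5 of 5 sets, exact permutation, adjusted p = 0.0648). Monocyte/macrophage-like cells made up 35.6% ± 13.4 in FOP and 22.6% ± 15.5 in WT, which did not pass (difference 12.9 points, exact permutation, adjusted p = 0.0770, higher in 4 of 5 sets). Fibroblast-like cells made up 26.4% ± 10.9 and 20.3% ± 7.12 (exact permutation, adjusted p = 0.0985, higher in 3 of 5 sets). Endothelial-like cells made up 8.0% ± 5.66 and 12.95% ± 7.25 (exact permutation, adjusted p = 0.0590, lower in 4 of 5 sets). This class left out the unnamed clusters 25, 15 and 14 (1185, 1692 and 642 cells), which scored for 13, 12 and 11 endothelial markers. Clusters 15 and 14 also scored for 5 adipocyte markers each. The share with these clusters included was not tested. In control muscle no class passed (smallest adjusted p = 0.878, exact permutation).

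Some of these calls on shares depended on the processing. The Schwann/glial-like call was lost without D1 WT injured 1 (adjusted p = 0.0532). The call on the mural-like share, FOP versus WT in injured muscle, was lost at Leiden resolution 0.5 (0.461), with doublets kept (0.501), and without undated FOP injured 1 or 2 (0.0506 each), D1 FOP injured 2 (0.0521) or D1 WT injured 1 (0.0532). With 1 UMI minimum per set and muscle the differences were -1.25 and -0.438 points. The endothelial-like share, FOP versus WT in injured muscle, passed with logit shares (0.0154), at Leiden resolutions 0.5 (0.0475) and 2.0 (0.0405) and among cells outside the immune classes (0.022). It also passed without D2 WT injured 2 (0.0428), D1 FOP injured 1 (0.0475), D4 FOP injured 1 (0.0448), D4 WT injured 2 (0.0495), D6 FOP injured 2 (0.00231) or D6 WT injured 2 (0.0365). It did not pass without the doubted libraries (0.136) or with 1 UMI minimum per set and muscle (0.23). The fibroblast-like share, FOP versus WT in injured muscle, passed among cells outside the immune classes (15.22 points, 0.00521) and without D6 WT injured 2 (0.0365), and was 2.135 points with 1 UMI minimum per set and muscle (0.682). The monocyte/macrophage-like share, FOP versus WT in injured muscle, passed with logit shares (0.0369) and without D2 WT injured 2 (0.0428), D4 WT injured 2 (0.0495) or D6 WT injured 2 (0.0365). The tenocyte-like share, FOP versus WT in injured muscle, passed without the doubted libraries (0.0478), D1 WT injured 2 (0.0333) or D6 WT injured 2 (0.0365).

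**Figure D1:**
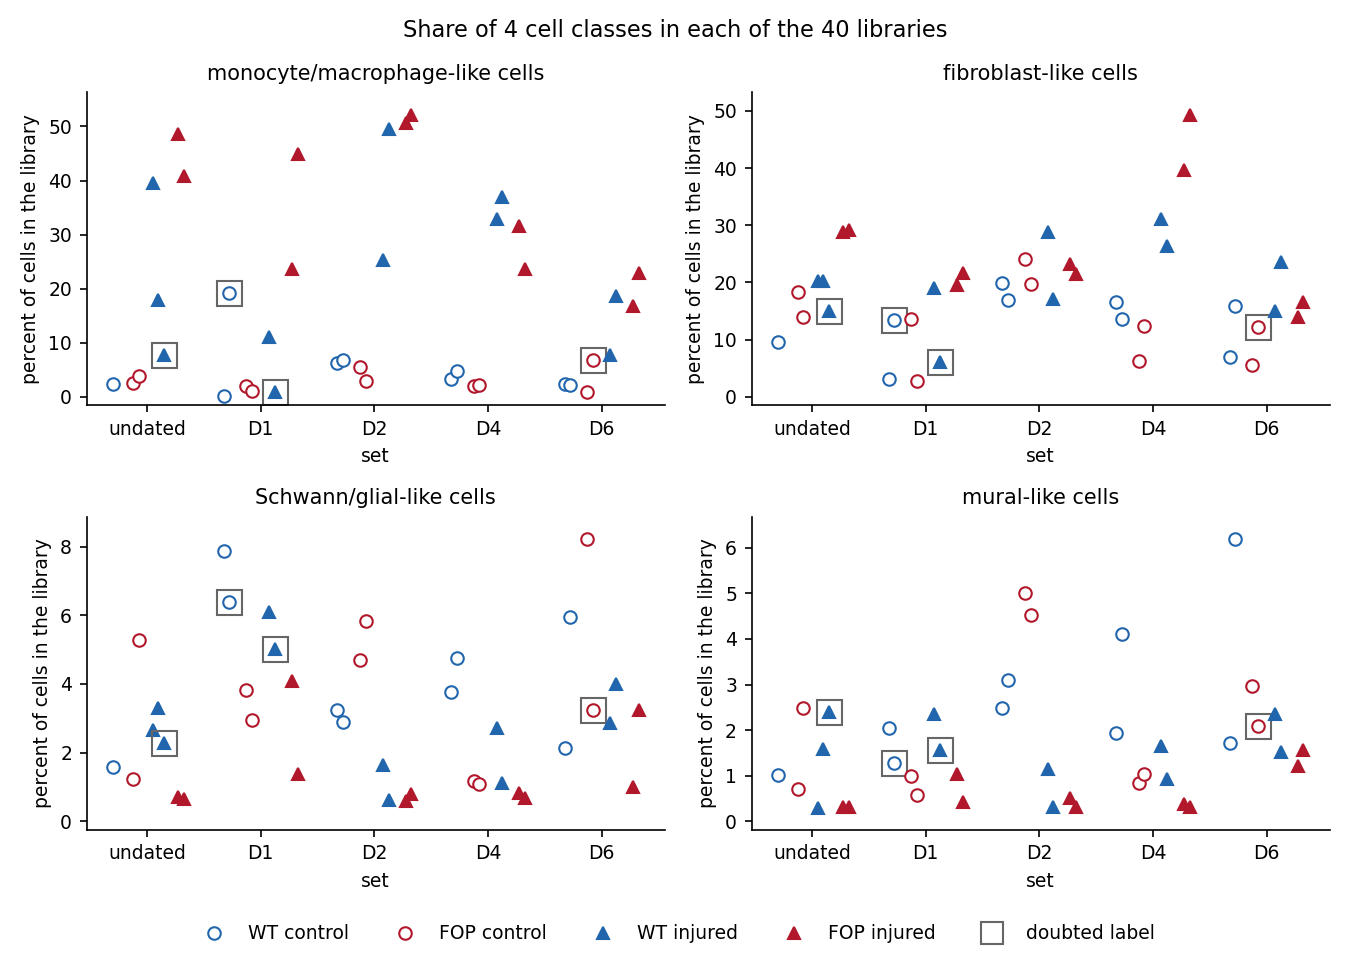
Percent of cells per library (y axis) in 4 cell classes by set (x axis), with 1 point per library, open circles for control and filled triangles for injured muscle, blue for WT and red for FOP; grey squares mark the 4 libraries with a doubted label. Monocyte/macrophage-like cells reach 52.2% in 1 injured library and 19.2% in 1 library labelled control, and the Schwann/glial-like mean is lower in FOP than in WT injured muscle in each of the 5 sets.

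Injured and control FOP muscle differed in the shares of 7 classes. Monocyte/macrophage-like cells rose by 32.6 points, from 3.01% ± 1.92 (SD, n = 10) in control to 35.6% ± 13.4 (n = 10) in injured libraries (exact permutation, adjusted p = 0.00193). Fibroblast-like cells rose by 13.5 points from 12.9% ± 6.71 (exact permutation, adjusted p = 0.00386). B cell-like cells fell by 21.38 points from 23.5% ± 11.7 to 2.16% ± 4.35 (exact permutation, adjusted p = 0.00193), and T cell-like cells fell by 15.9 points (adjusted p = 0.00836, exact). The lowest UMI count of a deposited barcode was 1899 to 5954 in FOP injured and 952 to 1622 in FOP control libraries. In FOP control muscle the median was 1957.5 UMIs in B cell-like and 2704 in T cell-like cells. This limit may therefore account for part of these falls and of the rises above, which was not tested. Schwann/glial-like, mural-like and neutrophil-like shares fell by 2.36, 1.49 and 0.361 points (exact permutation, adjusted p = 0.0193, 0.00463 and 0.00386). The call on the mural-like share, injured versus control muscle in FOP, was lost with cluster 13 included (-1.19 points, adjusted p = 0.405), with doublets kept (0.152) and at Leiden resolution 0.5 (0.351). The call on the Schwann/glial-like share, injured versus control muscle in FOP, was lost without D1 FOP injured 2 (0.0601) or D6 FOP injured 1 (0.0752). The endothelial-like share, injured versus control muscle in FOP, did not pass (-7.61 points, exact permutation, adjusted p = 0.0603) but passed among cells outside the immune classes (0.00116) and without the doubted libraries (0.0222), among others. In WT muscle no class passed. The largest differences there were 17.7 points for monocyte/macrophage-like cells (5.29% ± 5.64, n = 9, in control and 22.6% ± 15.5, n = 11, in injured libraries) and -12.3 points for B cell-like cells, both with an adjusted p of 0.0680 in the exact permutation test. Without the 4 doubted libraries 4 classes passed in WT, and leaving out the library labelled D1 WT injured 2 or D6 WT control 2 also gave 4.

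Fibroblast-like cells of injured muscle were compared between FOP and WT, the class that holds the fibro-adipogenic progenitors of muscle. In FOP, 11 of 17 measured genes that mark resident fibro-adipogenic progenitors were lower, and 14 when adjusted over the list alone (camera adjusted p = 1.74e-13). The list had an adjusted p = 0.249 with an estimated correlation and 0.00799 by fry. Gsn, an actin-severing protein, stood at 7485 ± 4800 CPM (SD, n = 10) against 22460 ± 18740 in WT (n = 11; log2 -1.51 ± 0.24, SE, adjusted p = 0.00412). Dcn, a small proteoglycan of the matrix, fell by 0.94 ± 0.16 and Smoc2, a secreted matricellular protein, by 1.21 ± 0.22 on the log2 scale (adjusted p = 0.00562 and 0.00729). The calls on Gsn and Dcn held in cluster 12 alone but were lost in clusters 2, 4 and 6 alone, where log2 values came down to -0.019 for Gsn (cluster 6) and -0.13 for Dcn (cluster 2). Smoc2 turned to 0.13 within cluster 6 and 0.12 within cluster 4. Higher in FOP were Ltbp2, which encodes a latent TGF-beta binding protein (log2 1.48 ± 0.38, adjusted p = 0.0285), and Il11, a cytokine induced by TGF-beta (0.90 ± 0.25, adjusted p = 0.0411), each in 5 of 5 sets. In all, 178 genes were higher and 416 lower of 10780 tested (edgeR); without the doubted libraries 44 were higher and 160 lower, and Ltbp2 and Il11 no longer passed (adjusted p = 0.0518 and 0.0965). With the flowcell as a further covariate, an alternative chosen after the data were seen, 64 were higher and 207 lower. The values of Ltbp2, FOP versus WT in injured muscle, fibroblast-like cells, were then 1.484 ± 0.40 (adjusted p = 0.0541).

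Of 25 immediate-early and dissociation genes, which respond to stress within minutes and also to tissue digestion, 12 were lower, and 18 adjusted over the list alone (camera adjusted p = 7.22e-14; adjusted p = 0.249 with an estimated correlation). Among them Jun, a subunit of the AP-1 transcription factor, stood at log2 -1.01 ± 0.14 (adjusted p = 0.00228), Fos, its partner, at -0.84 ± 0.16, and Socs3, an inhibitor of cytokine signalling, at -1.03 ± 0.21. Of 11 adipogenic genes 3 were lower, and 7 adjusted over the list alone (camera adjusted p = 0.00104; adjusted p = 0.363 with an estimated correlation), among them Fabp4, a fatty acid binding protein (-1.36 ± 0.29, adjusted p = 0.0152). The 34 collagen and matrix genes leaned higher by camera (adjusted p = 0.00104; adjusted p = 0.481 with an estimated correlation) and so did 22 proliferation genes (9.34e-08; adjusted p = 0.481 with an estimated correlation). In both lists 0 genes were called, over all genes or over the list alone. Myofibre transcripts, listed as possible carry-over, leaned lower (0 of 8 called, 6 adjusted over the list alone, camera adjusted p = 0.0111; adjusted p = 0.481 with an estimated correlation).

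Among 16 BMP/SMAD1/5 target genes, 1 was higher and 2 were lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.161; adjusted p = 0.577 with an estimated correlation; fry in its mixed form, adjusted p = 0.00174). Smad7, an inhibitory SMAD that both BMP and TGF-beta signals induce, was higher by 0.42 ± 0.11 in 5 of 5 sets (adjusted p = 0.0279). The value of Smad7, FOP versus WT in injured muscle, fibroblast-like cells, did not pass with the flowcell as a covariate (0.409 ± 0.11, adjusted p = 0.0528). Bmp4, which is a BMP ligand and itself on the list, fell by 1.07 ± 0.24, and Tob1, an antiproliferative protein, by 0.71 ± 0.17 (adjusted p = 0.0185 and 0.0227). Of 18 ligands and antagonists of the family 2 were lower, Bmp4 and Bmp2 (-0.90 ± 0.22, adjusted p = 0.0236), and 4 adjusted over the list alone (camera adjusted p = 0.194). The direction turned within cluster 4 (Bmp4 0.73, Bmp2 0.26) and cluster 12 (0.12 and 0.086). The values of the other genes always reported were not past the threshold. They were Runx2, the transcription factor that starts bone formation (0.72 ± 0.27, adjusted p = 0.118), Inhba, which encodes the subunit of activin A (0.51 ± 0.40, adjusted p = 0.451), Scx, a tendon transcription factor (0.39 ± 0.39), Id1, a BMP target (0.31 ± 0.36), Acvr1 (0.28 ± 0.17, adjusted p = 0.306) and Sox9, the transcription factor of cartilage (0.12 ± 0.19, adjusted p = 0.756). Between sets these values went in both directions. They ran from -1.55 ± 0.65 in D1 to 2.01 ± 0.53 in D4 for Id1, from -1.003 ± 0.32 in D1 to 0.717 ± 0.22 in D4 for Acvr1 and from -0.57 ± 0.43 in D1 to 1.16 ± 0.31 in D4 for Sox9. The test of the genotype by set interaction did not pass for them (adjusted p = 0.758, 0.675 and 0.798). The 8 measured chondrogenic genes had 0 calls (camera adjusted p = 0.472) and the 11 osteogenic genes 1 lower (adjusted p = 0.714). The 16 TGF-beta/activin target genes had 1 higher and 2 lower (adjusted p = 0.611) and the 9 receptors 0 (adjusted p = 0.401).

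Further genes higher in FOP fibroblast-like cells were Cda, cytidine deaminase (2.06 ± 0.58, from 5.63 ± 9.45 to 27.3 ± 40.8 CPM), Actg2, a smooth muscle actin (1.29 ± 0.33), Ncam1, a cell adhesion molecule (0.88 ± 0.22), Adam12, a metalloprotease (0.76 ± 0.22), and Pdk1, a kinase that restrains pyruvate oxidation (0.57 ± 0.17). Sets did not agree for 3 of these. Actg2 was -1.405 ± 2.45 in D1 and -4.27 ± 2.45 in D2 but 3.43 ± 0.54 in the undated set, Cda -0.53 ± 0.89 in D6 and Ncam1 -0.18 ± 0.75 in D1. With 1 library left out the Cda value ran from 1.66 to 3.14, and the calls on Cda, Adam12, Pdk1 and Il11 were lost in 14, 16, 16 and 15 of 21 fits. Lower were Clu, a secreted chaperone (-2.35 ± 0.33, adjusted p = 0.00228), Enpp2, which makes lysophosphatidic acid (-1.44 ± 0.21), Angptl7 (-1.93 ± 0.43) and Ccl11, the eosinophil chemokine eotaxin (-0.99 ± 0.20), each in 5 of 5 sets. Different clusters held much of this class in the genotypes. Cluster 6, led by Cthrc1, Tnc and Postn, held 40.2% ± 25.4 of FOP and 21.2% ± 19.997 of WT injured fibroblast-like cells, and cluster 12, led by Smoc2, Cxcl14 and Ccl11, held 15.7% ± 8.84 and 34.05% ± 15.3. DESeq2 called 968 genes. Counts depended on the set covariate (0 genes without it), on cell number (198 with at most 100 cells per library) and on a depth covariate added later (0). Within sets, edgeR called 7 genes higher in D1, 20 higher and 12 lower in D4, 3 higher in the undated set and 0 in D2 and D6. With 1 library left out in turn the count ran from 118 (without undated FOP injured 2) to 1214 (without undated WT injured 1), and it moved by over 1.5 times for 11 of 21 libraries. Leaving out the whole set D1 or D4, which leaves fewer libraries, lowered the count below this range.

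**Figure D2:**
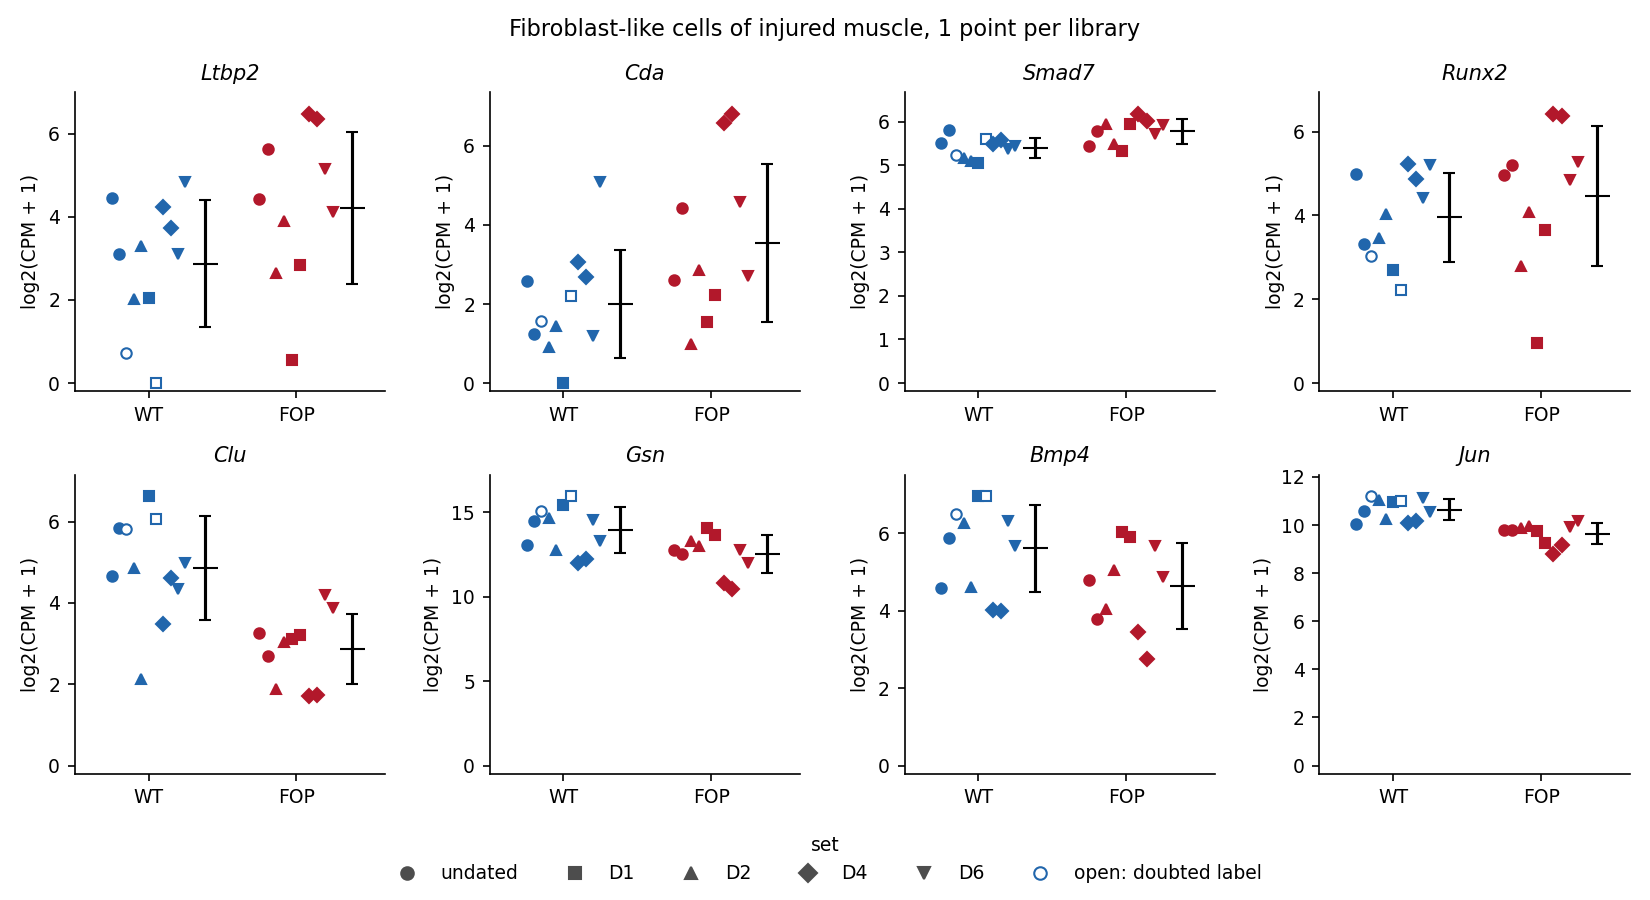
Level of 8 genes as log2(CPM + 1) on the y axis in fibroblast-like cells of injured muscle, with WT and FOP on the x axis, 1 point per library shaped by set, open points for libraries with a doubted label, and the mean with its SD as a black bar. Clu and Jun are lower in FOP in all 5 sets (log2 -2.35 and -1.01), while Runx2 overlaps between genotypes (adjusted p = 0.118).

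In monocyte/macrophage-like cells of injured muscle 2 genes were lower in FOP and 0 higher, of 9631 tested with 10 libraries in each group. They were Sgms1, a sphingomyelin synthase (-0.70 ± 0.11), and Dcn, a transcript typical of fibroblasts (24.3 ± 7.85 CPM in FOP, 68.6 ± 38.1 in WT; -1.45 ± 0.25), both at an adjusted p of 0.0419 and lower in 5 of 5 sets. At an unadjusted p under 0.05 there were 892 genes, and DESeq2 called 34. Acvr1 (0.02 ± 0.22, adjusted p = 0.993), Inhba (-0.43 ± 0.51), Id1 (-0.31 ± 0.28) and Runx2 (0.35 ± 0.25) did not pass, and Scx and Sox9 were too low to test. The 21 interferon response genes leaned higher (0 called, 2 adjusted over the list alone, camera adjusted p = 1.44e-07; adjusted p = 0.482 with an estimated correlation). The 25 immediate-early genes leaned lower (0 called, 11 adjusted over the list alone, 3.44e-13; adjusted p = 0.339 with an estimated correlation). So did 14 fibro-adipogenic progenitor genes (1 called, 1.08e-07; adjusted p = 0.339 with an estimated correlation). The 2 calls were lost in most alternatives, among them the flowcell covariate (0 genes), and leaving out undated WT injured 1 gave 22 genes while the count moved by over 1.5 times for 19 of 20 libraries.

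Endothelial-like cells of injured muscle carried 484 higher and 552 lower genes in FOP of 8006 tested (10 and 11 libraries; 216 and 254 without the doubted libraries). The class joins 2 clusters. Cluster 17, led by Plvap, Selp and Vwf, held 48.2% ± 17.04 of FOP and 27.2% ± 19.6 of WT injured endothelial-like cells, and cluster 21, led by Aqp1, Timp4 and C1qtnf9, held 51.8% and 72.8%. Within cluster 17 alone, an alternative chosen after the data were seen, 6 genes were higher and 55 lower, and within cluster 21 alone 85 and 55. Proliferation genes rose, with 11 of 22 called, and 16 adjusted over the list alone (camera adjusted p = 2.12e-09; adjusted p = 0.149 with an estimated correlation), among them the mitotic cyclin Ccnb2 (1.12 ± 0.26, adjusted p = 0.00755). The value of Ccnb2, FOP versus WT in injured muscle, endothelial-like cells, was 0.38 in cluster 17 alone (adjusted p = 0.313). So did 9 of 28 collagen and matrix genes, and 13 adjusted over the list alone (2.79e-06; adjusted p = 0.149 with an estimated correlation), including Fn1, fibronectin (1.53 ± 0.30), and Thbs1, thrombospondin (1.59 ± 0.26, adjusted p = 0.000781). Kcne3, a potassium channel subunit, was higher by 2.39 ± 0.49. Inhbb, which encodes a subunit of activin B, was higher by 1.03 ± 0.34 (adjusted p = 0.0443, and 0.143 without the doubted libraries). The call on Inhbb, FOP versus WT in injured muscle, endothelial-like cells, was also lost with the flowcell covariate (adjusted p = 0.0642). Of 25 immediate-early genes 20 were lower, and 22 adjusted over the list alone (1.86e-19; adjusted p = 0.118 with an estimated correlation). Of 20 interferon response genes 7 fell, and 9 adjusted over the list alone (9.77e-05; adjusted p = 0.277 with an estimated correlation), such as Isg15 (-0.79 ± 0.18). Of 9 antigen presentation genes 3 fell, and 4 adjusted over the list alone (0.00125; adjusted p = 0.277 with an estimated correlation), such as the class I gene H2-D1 (-0.61 ± 0.12). Of 16 BMP/SMAD1/5 targets 4 were lower, and 6 adjusted over the list alone (0.0025; adjusted p = 0.277 with an estimated correlation), with Xdh, xanthine dehydrogenase, at -1.47 ± 0.24. At Leiden resolution 0.5 Fn1 came down to 0.17, which did not pass. Transcripts typical of other cell types also moved, with Postn of fibroblast cluster 6 at 1.57 ± 0.39 (adjusted p = 0.0103, and 0.17 at Leiden resolution 0.5), Gsn at -1.72 ± 0.23, the macrophage product Retnla at -2.26 ± 0.58 and the neutrophil protein S100a8 at -2.80 ± 0.92 (lower in 3 of 5 sets). Postn stood at 50.8 CPM (cells pooled) in FOP and 13.9 in WT injured endothelial-like cells, against 2162 and 1847 in fibroblast-like and 11.5 and 9.05 in T cell-like cells. The count was 0 with a depth covariate, 3 without the set covariate, 92 at Leiden resolution 0.5, 178 with at most 5% mitochondrial UMIs and 420 with at least 50 cells.

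In muscle stem/progenitor-like cells (8 FOP and 9 WT libraries, 4856 genes) and T cell-like cells (6 and 9 libraries, 2976 genes) edgeR called 0 genes between genotypes in injured muscle. At an unadjusted p under 0.05 there were 480 and 346 genes, and DESeq2 called 1 and 0. Summed over all cells, 897 genes were higher and 1352 lower in FOP injured muscle of 13762 tested (148 and 440 without the doubted libraries), which includes differences in the makeup of cells. With the flowcell covariate 505 were higher and 840 lower. Ccl12, a monocyte chemoattractant, was higher (1.33 ± 0.39, adjusted p = 0.0339), with Adam12 (1.084 ± 0.28) and Nt5dc2 (1.05 ± 0.31). Lower were Chad and Comp, matrix proteins of cartilage and tendon (-2.62 ± 0.75 and -1.65 ± 0.43), Bmp6 (-1.69 ± 0.35), Angptl7 (-2.49 ± 0.68), the immunoglobulin chain Igkc (-2.79 ± 0.74) and the neutrophil transcript Retnlg (-5.26 ± 1.29). The value of Retnlg, FOP versus WT in injured muscle, all cells summed, was -2.96 without D6 WT injured 1 (adjusted p = 0.0522). Of 18 chondrogenic genes 5 fell, and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00429; adjusted p = 0.630 with an estimated correlation). Chad, Comp and Angptl7 are among the top genes of the tenocyte-like cluster 23. The tenocyte-like share was 0.383% ± 0.327 (n = 10) in FOP and 1.057% ± 0.882 (n = 11) in WT injured libraries, lower in 5 of 5 sets (-0.653 points, exact permutation, adjusted p = 0.0985). The total of 2249 was 0 without the set covariate and 0 with a depth covariate, and it ran from 320 (without undated FOP injured 2) to 3559 (without D2 WT injured 2) with 1 library left out, moving by over 1.5 times for 11 of 21.

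Control muscle, the left muscle of the labels, was compared between FOP and WT to ask for differences away from the injury. edgeR called 0 genes in each of 8 classes, with 10 FOP and 9 WT libraries for fibroblast-like cells and at least 5 per group in the others. At an unadjusted p under 0.05 there were 267 of 9160 genes in fibroblast-like, 183 of 4141 in monocyte/macrophage-like, 157 of 6484 in B cell-like, 125 of 4014 in Schwann/glial-like, 207 of 7023 in T cell-like, 224 of 8311 in endothelial-like, 86 of 2350 in mural-like and 85 of 2364 in muscle stem/progenitor-like cells. DESeq2 called 16 genes over the 8 classes together, and edgeR with the flowcell covariate 3. By camera, 10 adipogenic genes leaned higher in FOP fibroblast-like cells (0 called, 3 adjusted over the list alone, adjusted p = 0.00463; adjusted p = 0.871 with an estimated correlation) and 15 proliferation genes in monocyte/macrophage-like cells (0 called, also over the list alone, 1.24e-11; adjusted p = 0.325 with an estimated correlation). Of 19 such list calls over the 8 classes, 0 held with an estimated correlation.

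The response of fibroblast-like cells to injury was taken within each genotype. Cluster 6 (Cthrc1, Tnc, Postn) held 1.18% ± 2.89 of FOP and 1.58% ± 4.47 of WT control cells, against 40.2% and 21.2% in injured muscle. In WT, Spp1, the secreted matrix protein osteopontin, rose 80.3-fold (log2 6.33 ± 1.10, n = 11 injured and 9 control, adjusted p = 0.00566). Spp1 also leads macrophage cluster 5, so free RNA was compared, a test chosen after the data were seen. In WT injured libraries 20.7% of fibroblast-like cells had a Spp1 UMI (median depth 6298 UMIs), against 4.51% of T cell-like (3105) and 7.20% of endothelial-like cells (3385). Spp1 stood at 332.3, 14.9 and 23.3 CPM there, with cells of all libraries pooled (1.85, 0.556 and 1.80 in control muscle), while the macrophage transcript Lyz2 stood at 17.6, 19.6 and 28.4. Cthrc1, a collagen-associated secreted protein, rose by 5.44 ± 1.03, and Tnc, tenascin C, by 5.15 ± 1.26 (8.25 without D1 WT control 2). Scx (4.36 ± 0.89), Inhba (2.48 ± 0.37, adjusted p = 0.00388) and Runx2 (2.23 ± 0.45, adjusted p = 0.0103) rose as well, as did the cyclin Ccnb1 (3.92 ± 0.61) and Lrrc15, a marker of activated fibroblasts (5.77 ± 0.96). Gsn (-1.33 ± 0.37), Dcn (-0.89 ± 0.23), Bmp4 (-1.15 ± 0.30), Bmp2 (-1.22 ± 0.28), the methyltransferase gene Inmt (-1.82 ± 0.40) and Sult1e1, an oestrogen sulfotransferase (-2.56 ± 0.59), fell. In all, 605 genes rose and 481 fell of 9905 tested; without the 4 doubted libraries, 2007 rose and 1971 fell. With 1 library left out the calls on Gsn, Bmp4 and Dcn were lost in 10, 7 and 6 of 20 fits. The count was 3378 without D1 WT control 2 and 145 without D4 WT control 1, and moved by over 1.5 times for 14 of 20 libraries. It was 166 without the set covariate and 329 with at most 100 cells.

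In FOP, 2639 genes rose and 2665 fell of 10167 in fibroblast-like cells (10 libraries each, with 3017 and 2532 without the doubted libraries). No alternative that was run moved this count by over 1.5 times (4927 to 5549 with 1 library left out). A depth covariate was not among them, although median UMI counts per cell were 6890 in FOP injured and 2685 in FOP control libraries. Cxcl5, a neutrophil chemoattractant, rose 202.9-fold (7.67 ± 0.58, adjusted p = 3.61e-08), Spp1 by 6.92 ± 0.72, Cthrc1 by 5.58 ± 0.63, Tnc by 4.71 ± 0.94, the proliferation marker Mki67 by 4.12 ± 0.40 and Runx2 by 2.80 ± 0.48. Inhba (2.87 ± 0.54) and Acvr1 (0.81 ± 0.17, adjusted p = 0.000656) rose too, and are named here after their values were seen. Gsn (-2.90 ± 0.28), Clu (-2.97 ± 0.34), Angptl7 (-3.44 ± 0.43), Inmt (-2.94 ± 0.32), Dcn (-1.81 ± 0.19), Jun (-1.59 ± 0.18), Bmp4 (-2.05 ± 0.30) and Bmp2 (-1.73 ± 0.19) fell.

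By list, 16 of 22 proliferation genes rose in WT and 21 of 22 in FOP fibroblast-like cells (camera adjusted p = 2.25e-13 and 2.17e-14; with an estimated correlation, adjusted p = 0.4 and 0.202), and 19 and 21 adjusted over the list alone. Collagen and matrix genes rose in 16 of 34 in WT, with 0 falling, and in 25 of 34 in FOP, with 2 falling (1.53e-09 and 1.7e-05; with an estimated correlation, adjusted p = 0.4 and 0.221). Of 15 BMP/SMAD1/5 targets 5 fell in WT, and 7 adjusted over the list alone (0.0141; adjusted p = 0.447 with an estimated correlation). In FOP 7 of 16 fell and 2 rose (0.0183; adjusted p = 0.210 with an estimated correlation). Hypoxia and glycolysis genes rose in 8 of 23 in WT, and 14 rose and 4 fell of 23 in FOP (0.000606 and 5.52e-05; with an estimated correlation, adjusted p = 0.4 and 0.299). Immediate-early genes fell in 9 and 22 of 25 (8.03e-08 and 2.67e-10; with an estimated correlation, adjusted p = 0.4 and 0.202). Fibro-adipogenic progenitor genes fell in 8 and 15 of 17 (3.72e-07 and 5.64e-09; with an estimated correlation, adjusted p = 0.4 and 0.202). All these counts include the doubted libraries. Without them the genes called for injury went from 1086 to 3978 in WT and from 5304 to 5549 in FOP. The smaller counts in WT therefore do not show a weaker response there.

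**Figure D3:**
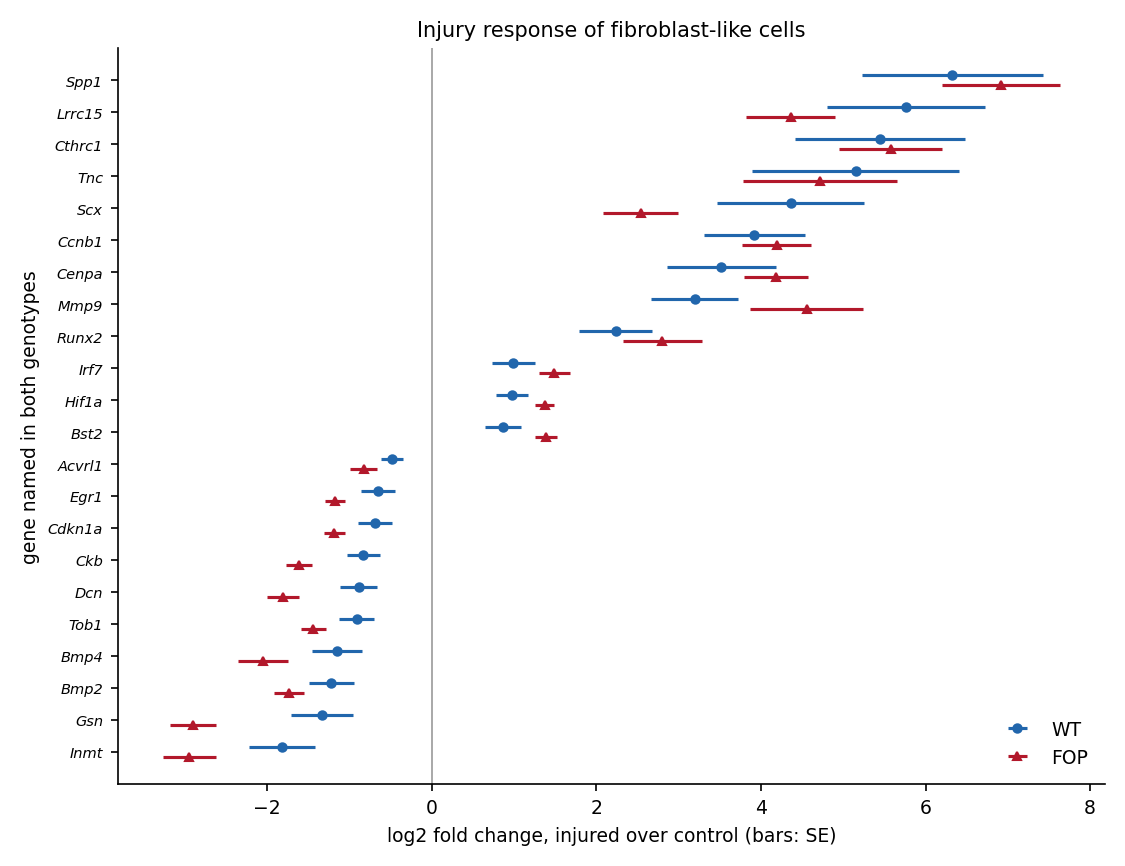
Log2 fold change of injured over control muscle (x axis, bars are SE) in fibroblast-like cells for the 22 genes (y axis) named in both genotypes, blue circles for WT and red triangles for FOP. The rule named only genes past the threshold, so each had passed in both genotypes and the 22 do not stand for all genes. All 22 have the same sign in both, and 19 lie farther from 0 in FOP (22 and 19 also without the doubted libraries); of the 22, only Gsn passes the test of the genotype by injury interaction (log2 -1.63 ± 0.31, adjusted p = 0.0298).

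Monocyte/macrophage-like cells had genes past the threshold for injury in both genotypes, and the clusters that make up the class differed too. Cluster 9 held 75.2% ± 17.1 of FOP and 69.8% ± 26.9 of WT control cells but 16.6% ± 7.501 and 31.99% ± 26.5 of injured ones. Cluster 5 held 7.38% ± 15.4 and 2.08% ± 2.61 of control and 45.6% ± 25.3 and 39.0% ± 25.8 of injured ones. Sets differed as well. Cluster 5 had 77 cells in D1, 646 in D2, 971 in D4, 495 in D6 and 1098 in the undated set. In the same order cluster 0, led by Chil3 and Clec4e, had 1041, 1048, 183, 121 and 230. Fibroblast cluster 6 had 113, 163, 1261, 326 and 358. The sets may thus not stand for 1 stage of the injury, which was not tested. In WT (10 injured and 8 control libraries), Spp1 rose by 8.0 ± 1.44 (adjusted p = 0.00865), Mmp12, macrophage elastase, by 4.81 ± 1.09 (10.94 without D1 WT control 2), Gpnmb, a glycoprotein of phagocytes, by 4.30 ± 1.02, the lipid receptor Trem2 by 3.33 ± 0.64 and the fatty acid binding protein Fabp5 by 3.11 ± 0.61. The resident macrophage receptor Timd4 (-3.40 ± 0.67), Retnla (-3.43 ± 0.85), the lectin Cd209a (-4.01 ± 0.51) and Siglech (-3.77 ± 0.67) fell. In FOP (10 and 8 libraries), Spp1 rose by 7.495 ± 0.90 and Gpnmb by 4.93 ± 0.57 (11.7 and 8.83 without D6 FOP control 2, which was doubted), Mmp12 by 4.32 ± 0.51 and the mucin-type protein Pdpn by 5.49 ± 0.44 (adjusted p = 2.47e-08). Retnla (-5.36 ± 0.44), the lectin Mgl2 (-4.97 ± 0.37), Timd4 (-4.09 ± 0.39), the haemoglobin scavenger receptor Cd163 (-2.96 ± 0.31) and Cd74, the invariant chain of class II (-1.53 ± 0.23), fell. In WT 381 genes rose and 382 fell of 7689 (963 and 1035 without the doubted libraries), and in FOP 1270 rose and 1133 fell of 9258 (1606 and 1146). In FOP the 25 immediate-early genes (21 fell, and 22 adjusted over the list alone, camera adjusted p = 5.18e-20) and 3 tendon genes (Egr1, Egr2 and Angptl7, all falling, 7.48e-05) held with an estimated correlation (adjusted p = 0.0196 each). Hypoxia and glycolysis genes rose in 8 of 22 in WT and in 15 of 24 in FOP, with 1 falling there (camera adjusted p = 1.49e-05 and 1.41e-12; with an estimated correlation, adjusted p = 0.963 and 0.151). The WT count ran from 136 (without D2 WT control 2) to 1559 (without D1 WT injured 1) and moved by over 1.5 times for 13 of 18 libraries. It was 20 without the set covariate, 418 with the flowcell covariate and 372 with at most 5% mitochondrial UMIs, and the FOP count was 1314 with at least 50 cells.

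In endothelial-like cells of FOP muscle, 1505 genes rose and 1673 fell with injury (10 libraries each, of 8080; 1654 and 1784 without the doubted libraries). Cluster 17 held 12.2% ± 3.40 of FOP and 11.8% ± 9.42 of WT control endothelial-like cells, against 48.2% and 27.2% in injured muscle. Kcne3 (5.45 ± 0.73), the angiogenic factors Pgf (3.65 ± 0.53) and Apln (3.41 ± 0.47), Inhbb (2.80 ± 0.32, adjusted p = 5.61e-07), Bmp2 (2.45 ± 0.50) and the thymidine kinase Tk1 (4.13 ± 0.46) rose. Xdh (-1.91 ± 0.24) and Id3, a direct BMP target (-0.87 ± 0.11, adjusted p = 1.73e-06), fell, as did the myelin transcript Mbp (-3.49 ± 0.46), typical of Schwann cells. Of 16 BMP/SMAD1/5 targets 10 fell, and 11 adjusted over the list alone (camera adjusted p = 5.6e-05; adjusted p = 0.160 with an estimated correlation), while 6 of 7 ligands and antagonists rose (0.00692; adjusted p = 0.160 with an estimated correlation). In WT, 28 genes rose and 6 fell of 8340 (11 and 9 libraries; 865 and 774 without the doubted libraries), with Ccnb2 at 3.46 ± 0.56, the neuropeptide gene Gal at 3.86 ± 0.85, Id4 at -1.19 ± 0.26 and Tob1 at -0.70 ± 0.14. The WT count was 0 without the set covariate and 0 with at most 100 cells, 246 with the flowcell covariate and 168 by DESeq2; the FOP count was 777 with at most 5% mitochondrial UMIs and 1100 at Leiden resolution 0.5.

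Muscle stem/progenitor-like cells of WT changed in 580 genes of 3192, 266 higher and 314 lower (10 and 9 libraries; 746 and 743 without the doubted libraries). Spp1 rose by 7.79 ± 1.22, the embryonic and cardiac troponin Tnnt2 by 7.18 ± 1.33, Postn, periostin, by 5.30 ± 0.83 and the topoisomerase Top2a by 4.50 ± 0.80, while the natriuretic peptide gene Nppc fell by 2.22 ± 0.65. The class joins 2 clusters, of which cluster 7 (Myog, Actc1, Tnnt2) held 0.965% ± 1.92 of WT and 0.817% ± 2.45 of FOP control cells, against 32.2% ± 36.1 and 56.3% ± 35.9 of injured ones. In FOP 817 genes rose and 806 fell of 4048 (8 and 7 libraries in 4 sets; 836 and 776 without the doubted libraries), with Birc5, survivin, at 6.35 ± 0.61, Tnc at 5.88 ± 0.69, Bmp4 at -2.66 ± 0.60 and the BMP targets Rgcc at -2.62 ± 0.35 and Bambi at -2.23 ± 0.30. Of 8 measured BMP/SMAD1/5 targets 6 fell in FOP (camera adjusted p = 0.00109; adjusted p = 0.163 with an estimated correlation) and 3 in WT (0.00276; adjusted p = 0.354 with an estimated correlation). These counts were 32 in WT with at least 50 cells and 168 in FOP with at most 5% mitochondrial UMIs.

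The remaining classes had few or no calls with injury. T cell-like cells of FOP carried 4 higher and 19 lower genes of 3861 (6 and 8 libraries; 37 and 55 without the doubted libraries), with the replication factor Mcm7 at 0.99 ± 0.20, the nuclear transport GTPase Ran at 0.79 ± 0.17 and Rps27, a ribosomal protein, at -1.28 ± 0.23. This count was 0 without the set covariate or with at least 50 cells and 106 by DESeq2. In WT, Schwann/glial-like cells had 1 higher gene, the tubulin Tubb2b (1.499 ± 0.24, adjusted p = 0.0178, 9 and 9 libraries; 15 genes by DESeq2). Their 17 collagen and matrix genes leaned higher (0 called, 1 adjusted over the list alone, camera adjusted p = 2.15e-06), a call that held with an estimated correlation (adjusted p = 0.00403). edgeR called 0 genes in WT B cell-like cells (98 at an unadjusted p under 0.05, 1 by DESeq2) and 0 in WT T cell-like cells (163 and 2). In the latter the 4 measured inflammatory monocyte genes leaned higher (0 called, 2 adjusted over the list alone, camera adjusted p = 8.87e-06), which held with an estimated correlation (adjusted p = 0.0178). Lymphocytes are also known to express some of these, such as Ly6c2. In WT injured libraries, where monocyte/macrophage-like cells made up 22.6% against 5.29% in control, T cell-like cells held Ly6c2 at 533.8 CPM (cells pooled), against 255.6 in monocyte/macrophage-like and 6.73 in Schwann/glial-like cells. Lyz2 stood at 19.6 CPM in T cell-like cells of injured and 13.1 in those of control muscle.

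Whether the injury response differed between genotypes was tested as an interaction, over 40 libraries in fibroblast-like and 36 in monocyte/macrophage-like cells. In fibroblast-like cells 15 genes passed of 10791, each with a more negative response in FOP, led by Adipoq, the adipocyte hormone adiponectin (-6.19 ± 1.25, adjusted p = 0.0298, of which the difference in injured muscle was -1.875 and that in control muscle 4.311), Clu (-2.78 ± 0.58), Fabp4 (-2.21 ± 0.48) and Gsn (-1.63 ± 0.31). At an unadjusted p under 0.05 there were 1544 genes, DESeq2 called 161, and 0 passed without the doubted libraries, where Gsn stood at an adjusted p of 0.0604. Of 11 adipogenic genes 2 passed, and 8 adjusted over the list alone (camera adjusted p = 9.77e-06; adjusted p = 0.141 with an estimated correlation). Of 17 fibro-adipogenic progenitor genes 1 passed, and 11 adjusted over the list alone (1.41e-12; adjusted p = 0.126 with an estimated correlation). The count of 15 ran from 0 (without D2 WT injured 1, among others) to 129 (without undated WT injured 1) and moved by over 1.5 times for 27 of 40 libraries. In monocyte/macrophage-like cells edgeR called 0 of 9224 genes (600 at an unadjusted p under 0.05, 0 by DESeq2, smallest adjusted p = 0.0536). Whether the difference between genotypes in injured muscle varied between sets was tested as a second interaction. edgeR called 0 genes in fibroblast-like cells (634 at an unadjusted p under 0.05, 17 by DESeq2, smallest adjusted p = 0.109) and 0 in monocyte/macrophage-like cells (386, 5 by DESeq2, smallest adjusted p = 0.960).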

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

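The tests of cluster makeup, of the doubted libraries and of the Schwann/glial-like and mural-like shares were chosen only after the result was seen.

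The makeup of cells and the endothelial-like expression of 3 libraries went against their labels. In the library labelled D1 WT control 2 monocyte/macrophage-like cells made up 19.2%, far above the nearest other WT control library (6.81%). A score of genes that respond to injury, learned in endothelial-like cells of the FOP libraries of the other sets, was higher there by 2.12 than in the library labelled D1 WT injured 2, close to the mean gap of 2.30 between injured and control FOP libraries of that set. Exchanged labels of this pair are therefore a candidate explanation. The library labelled undated WT injured 3 lay at 0.00325 on a scale from the control (0) to the injured mean (1) of its set, so an uninjured muscle under that label is likewise a candidate explanation (a weak injury was not tested). A shallow library is argued against as the cause in D1 WT injured 2, where monocyte/macrophage-like cells remained at 0.679% under 1 UMI minimum for its set, against at least 12.47% in the other injured D1 libraries. The fourth doubted library, D6 FOP control 2, scored 0.122. This was above the other D6 control libraries (-0.747, -1.091 and -0.799) and D6 WT injured 1 (-0.383), but below the other D6 injured libraries (0.556, 1.016 and 1.205). No explanation was tested for it.

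Genes that differ between FOP and WT fibroblast-like cells of injured muscle may reflect a stronger course of the same injury response. Across the expressed genes, called or not, fold changes between genotypes in some sets correlated with those of injury in WT libraries of the other sets in 20 of 20 splits of the sets (r from 0.358 to 0.666). The splits reuse the same 5 sets and are not independent. Median UMI counts per cell rose from WT control (2725) to WT injured (5125) and FOP injured libraries (6890). Cluster 6 held 1.58%, 21.2% and 40.2% of fibroblast-like cells there. Either could give such a correlation, so it cannot tell a stronger course apart from them. The doubted libraries as the whole cause are argued against, since without them the median ratio of fold changes was 0.896 (593 called genes measured). Of these genes 200 still passed, and all had been called with the doubted libraries included. A part played by these libraries is not excluded. Depth per cell cannot be told apart from genotype: its trend among control libraries would give a median of 0.609 of the observed changes (0.355 without D1 WT control 2, 0.318 without both doubted control libraries), and with depth as a covariate the median change went from 0.614 to 0.217 while the median SE went from 0.153 to 0.166. Nor can the makeup of clusters, since within clusters a median ratio of 0.5 was left and 98.2% of genes kept their sign.

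Lower Schwann/glial-like and mural-like shares in FOP injured muscle were weighed against 3 technical explanations. For the Schwann/glial-like share each as the whole cause is argued against: the adjusted p was 0.0351 with 1 UMI minimum per set and muscle, 0.00139 among cells outside the immune classes and 0.0478 without the doubted libraries, and over all alternatives, single libraries left out included, it ran from 0.00139 to 0.0532. With the common UMI minimum the differences shrank from -1.56 to -1.25 and from -0.83 to -0.438 points, so depth may be part of the cause. The mural-like call depended on where cells were drawn into the class, since with the unnamed cluster 13 included it did not pass (-2.82 points, lower in 5 of 5 sets, adjusted p = 0.0648). Among cells outside the immune classes the fibroblast-like share was higher in FOP, and whether this lowered the Schwann/glial-like share was not tested. Fewer Schwann/glial-like cells in FOP lesions remain a hypothesis that counts of cells per muscle would have to test.

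A library far from the others of its group was found in 5 of 43 combinations of a measure and a group, where chance gives about 1 in 20. Among FOP injured libraries, D6 FOP injured 1 held 13.99% B cell-like cells (next 3.61%) and 25% T cell-like cells (next 6.59%). D6 FOP injured 2 held 4.58% cells of the unnamed cluster 25 (next 2.53%). Among WT control libraries, besides D1 WT control 2 above (19.24%), D4 WT control 2 held 6.25% cells of the unnamed cluster 14 (next 1.83%).

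The interaction test called 15 genes in fibroblast-like cells, all with a more negative response to injury in FOP. They were Adipoq (-6.19), Clu (-2.78), Fabp4 (-2.21), Gsn (-1.63), Sult1a1 (-1.61), Enpp2 (-1.57), Vwa1 (-1.52), Agmo (-1.51), Sparcl1 (-1.46), Pnpla2 (-1.34), Gstm1 (-1.22), Plscr4 (-1.11), Jun (-1.02), Sipa1 (-0.97) and Tppp3 (-0.82), on the log2 scale. Most of the Adipoq value came from control muscle, where the estimate of FOP over WT was 4.31 ± 1.14 (SE), against -1.875 in injured muscle. For Pnpla2 and Fabp4 the control estimates were 0.63 ± 0.22 and 0.87 ± 0.35, and in the test of control muscle 0 genes passed. Without the doubted libraries 0 of the genes passed, and the count went from 0 to 129 with single libraries left out and moved by over 1.5 times for 27 of 40. The genes outside the naming rule are listed after their values were seen.

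Counts were found on vector features that no comparison used: SV40 14166, EC18 1096, PGK 26 and mFc 9 UMIs over all libraries.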

How the results depend on the processing

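The depth and flowcell covariates, the fits without the doubted libraries, the single clusters, cluster 13 counted as mural-like and the common UMI minimum were chosen only after the result was seen. No paired analysis was possible because the labels name no animals. Where no cause is given, the cause was not tested. Counts are genes past the threshold, out of the count in the report. In FOP fibroblast-like cells the count of 5304 genes for injury stayed within 1.5 times under each alternative run. The depth covariate was run only for FOP against WT in injured muscle, so counts for injury were not tested against depth. At least 50 cells, doublets kept and Leiden resolution 0.5 gave no value for mural-like cells of control muscle, and at least 50 cells none for FOP muscle stem/progenitor-like cells.

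For FOP against WT in injured muscle, fibroblast-like cells (594) gave 968 with DESeq2, 1016 with no filter, 0 with no set covariate, 198 with at most 100 cells, 0 with the depth covariate and 271 with the flowcell covariate. They gave 113, 13 and 31 without the undated, D1 and D4 sets, which leaves fewer libraries, and 204 without the doubted libraries. Cluster 6 alone gave 0, all but cluster 6 gave 315, and clusters 2, 4 and 12 alone 65, 0 and 84. Single libraries left out gave 118 (undated FOP injured 2) to 1214 (undated WT injured 1). Monocyte/macrophage-like cells (2) gave 34 with DESeq2 and 380 with no filter. They gave 0 with no set covariate, at most 100 cells, the Y to Xist covariate, the depth covariate, the flowcell covariate, without set D2, D1 or D4 and in clusters 0 and 5 alone. They gave 1 with doublets kept, at most 5% mitochondrial UMIs, without the undated set and with cluster 1, and 64 in cluster 9 alone. Single libraries left out gave 0 to 22 (undated WT injured 1). T cell-like and muscle stem/progenitor-like cells (0) gave 1 with DESeq2 and 416 with no filter. Endothelial-like cells (1036) gave 420 with at least 50 cells, and 3 with no set covariate. They gave 178 with at most 5% mitochondrial UMIs, 92 at Leiden resolution 0.5, 0 with the depth covariate and 470 without the doubted libraries. Clusters 17 and 21 alone gave 61 and 140. All cells summed (2249) gave 0 with no set covariate, 0 with the depth covariate, 1345 with the flowcell covariate, 588 without the doubted libraries and 320 (undated FOP injured 2) to 3559 (D2 WT injured 2) with single libraries left out.

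In control muscle the 0 calls by edgeR became 16 with DESeq2, 220 with no filter, and 5 with at least 50 cells. They became 2 with at most 5% mitochondrial UMIs, 2 with at most 100 cells, 3 with the flowcell covariate, 1 without the doubted libraries and 0 to 1 (D4 FOP control 1) with single libraries left out. For injury in WT, fibroblast-like cells (1086) gave 2258 with no filter, 166 with no set covariate, and 329 with at most 100 cells. They gave 3978 without the doubted libraries and 145 (D4 WT control 1) to 3378 (D1 WT control 2) with single libraries left out. Monocyte/macrophage-like cells (763) gave 1599 with no filter, and 20 with no set covariate. They gave 418 with the flowcell covariate, 372 with at most 5% mitochondrial UMIs, 1998 without the doubted libraries and 136 (D2 WT control 2) to 1559 (D1 WT injured 1). B cell-like, T cell-like and Schwann/glial-like cells together (1) gave 18 with DESeq2, 254 with no filter, 0 with no set covariate, 0 with doublets kept, 2 with the flowcell covariate and 32 without the doubted libraries. Endothelial-like cells (34) gave 168 with DESeq2, 795 with no filter, and 0 with no set covariate. They gave 14 with at most 5% mitochondrial UMIs, 1 at Leiden resolution 0.5, 0 with at most 100 cells, 246 with the flowcell covariate and 1639 without the doubted libraries. Muscle stem/progenitor-like cells (580) gave 1186 with no filter, 32 with at least 50 cells, 277 with no set covariate and 1489 without the doubted libraries.

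For injury in FOP, monocyte/macrophage-like cells (2403) gave 1314 with at least 50 cells. T cell-like cells (23) gave 106 with DESeq2, 224 with no filter, 0 with at least 50 cells, 0 with no set covariate and 92 without the doubted libraries. Endothelial-like cells (3178) gave 777 with at most 5% mitochondrial UMIs and 1100 at Leiden resolution 0.5. Muscle stem/progenitor-like cells (1623) gave 168 with at most 5% mitochondrial UMIs. The interaction in fibroblast-like cells (15) gave 161 with DESeq2, 521 with no filter, 33 with at least 50 cells, and 0 with no set covariate. It gave 9 with doublets kept, 2 with at most 100 cells, 0 without the doubted libraries and 0 (D2 WT injured 1 among others) to 129 (undated WT injured 1) with single libraries left out. In monocyte/macrophage-like cells (0 by edgeR) it gave 122 with no filter, 1 with at most 5% mitochondrial UMIs, 2 at Leiden resolution 2.0 and 0 to 2 with single libraries left out. The genotype by set interaction (0 by edgeR) gave 17 with DESeq2, 575 with no filter and 0 to 4 (D6 WT injured 1) in fibroblast-like cells. In monocyte/macrophage-like cells it gave 5 with DESeq2, 290 with no filter, 1 without the doubted libraries and 0 to 1 (undated WT injured 3).

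Classes whose share passed between genotypes in injured muscle (2) became 1 with cluster 13 counted as mural-like, 7 with logit shares and 4 at Leiden resolution 2.0. They became 4 among cells outside the immune classes, 5 without the doubted libraries and 0 (D1 WT injured 1) to 8 (D6 WT injured 2) with single libraries left out. For injury in WT (0) they became 2 among cells outside the immune classes, 4 without the doubted libraries, 6 with 1 UMI minimum per set and muscle and 0 to 4 (D1 WT injured 2 or D6 WT control 2). That minimum stayed higher in injured than in control muscle in each set, as with 5954 against 1811 in the undated set. It therefore cannot decide whether depth plays a part in the comparison of injured with control muscle. The difference in the B cell-like share between genotypes went from -5.13 to 0.123 points with 1 UMI minimum per set and muscle. Gene lists past the threshold went, with an estimated correlation, from 50 to 0 between genotypes in injured muscle, and from 19 to 0 in control muscle. They went from 40 to 2 for injury in WT, from 43 to 2 in FOP and from 13 to 0 for the interaction. Without the doubted libraries they were 10 in control muscle and 8 for the interaction.

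These log2 differences between genotypes in injured muscle changed sign. In fibroblast-like cells Smoc2 was 0.13 in cluster 6 alone and 0.12 in cluster 4 alone. Bmp4 was 0.73 in cluster 4 and 0.12 in cluster 12, Bmp2 0.26 and 0.086 in the same clusters, and Ccl11 0.050 in cluster 6. With the depth covariate Runx2 was -0.031, Inhba -0.35 and Scx -0.45. In cluster 6 alone Inhba was -0.030 and Scx -0.12, and Scx was -0.096 with the Y to Xist covariate. Id1 was -0.23 without set D4, -0.82 without cluster 6, -0.86 in cluster 4 and -0.88 in cluster 12. The values of Sox9, FOP versus WT in injured muscle, fibroblast-like cells, were -0.17, -0.23, -0.00337 and -0.84 in those 4 fits. Acvr1 was -0.040 without cluster 6. The values of Acvr1, FOP versus WT in injured muscle, monocyte/macrophage-like cells, were -0.089 with no set covariate and -0.0008259 at Leiden resolution 2.0. It was -0.048, -0.016 and -0.061 without sets D2, D1 and D4, and -0.079 (D4 WT injured 1) to 0.12 (D6 WT injured 1) with single libraries left out. Inhba there was 0.10 without set D4 and -0.69 to 0.16 (D4 WT injured 1). Id1 was 0.35 with the depth covariate, 0.12 without set D1, 0.58 in cluster 5 alone and -0.46 to 0.12 (D1 WT injured 1), and Runx2 was -0.058 with the depth covariate. Retnla in endothelial-like cells was 0.22 with the depth covariate.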

Other observations

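Some transcripts had no counts in control muscle. Arg1, the arginase of repair macrophages, had 8729 UMIs in monocyte/macrophage-like cells of 10 FOP injured libraries and 0 in 8 control libraries, at least 159-fold higher against a floor of 3 counts over the group. Runx2 in FOP muscle stem/progenitor-like cells had 289 UMIs over 8 injured libraries, of which 6 held any, and 0 in 7 control libraries, at least 11.4-fold higher against the same floor.

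Other splits of the same libraries were fitted in the same way. The rule for excluding chance was that under 5% of the splits gave as many genes, the real split included. It was not corrected for the number of results, so single results could still meet it by chance. The splits treat libraries as independent, but the labels name no animals. If libraries of 1 group share an animal, the real split could stand out without an effect of genotype or injury. Between genotypes in injured muscle the rule was met, with no other split calling as many genes, for fibroblast-like cells (1 of 100 splits, 594 genes, highest other 4), endothelial-like cells (1 of 100, 1036 genes, highest other 3) and all cells summed (1 of 60, 2249 genes, highest other 3). Monocyte/macrophage-like cells met the rule too (2 of 100, 2 genes), but another split gave as many genes (highest other 2), so chance is not excluded there. For T cell-like and muscle stem/progenitor-like cells the real count by edgeR is 0, which each of 100 splits reaches by construction, so the splits say nothing about chance there (highest other 3 and 342).

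In control muscle the real count by edgeR is 0 in each of 8 classes, so that 100 of 100 splits reach it by construction and say nothing about chance. The highest other split called 5 genes in fibroblast-like, 3 in monocyte/macrophage-like, 186 in B cell-like, 7 in Schwann/glial-like, 6 in T cell-like, 7 in endothelial-like, 18 in mural-like and 3 in muscle stem/progenitor-like cells.

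For injury in WT, the rule was met for fibroblast-like (2 of 100 splits, 1086 genes, highest other 1089), monocyte/macrophage-like (2 of 100, 763 genes, highest other 2030), endothelial-like (1 of 100, 34 genes, highest other 3) and muscle stem/progenitor-like cells (2 of 100, 580 genes, highest other 1389). In these classes, endothelial-like cells apart, another split called more genes than the real one, so chance is not excluded there. Splits that call over 2 times the real count may reflect a structure of the samples, but what those splits share was not tested. Chance cannot be excluded for Schwann/glial-like cells (5 of 100, 1 gene, highest other 1). For B cell-like and T cell-like cells the real count is 0, which 100 of 100 splits reach by construction (highest other 20 and 7).

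For injury in FOP, the rule was met, with no other split calling as many genes, for fibroblast-like (1 of 100 splits, 5304 genes, highest other 4825), monocyte/macrophage-like (1 of 100, 2403 genes, highest other 915), T cell-like (1 of 100, 23 genes, highest other 16), endothelial-like (1 of 100, 3178 genes, highest other 2299) and muscle stem/progenitor-like cells (1 of 100, 1623 genes, highest other 764). For the genotype by injury interaction the rule was met in fibroblast-like cells (1 of 40 splits, 15 genes, highest other 1). Without the doubted libraries 0 genes passed there. In monocyte/macrophage-like cells the real count is 0, which 40 of 40 splits reach by construction (highest other 2). The same holds for the genotype by set interaction in fibroblast-like and monocyte/macrophage-like cells (50 of 50 splits each, highest other 261 and 591). What the splits with many genes share was not tested.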
